A study of Vitis vinifera with 6 samples.

How the data were processed

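RNA was extracted from pooled deseeded berries and made into stranded mRNA libraries, per the labels' protocols. The labels give 10 berries from the first cluster of each of 7 vines as the pool of a plot. The field layout was a randomized complete block design with 4 plots per treatment, of which 3 were sequenced. STAR 2.7.9a and RSEM 1.3.3 are named in the submitters' processing notes; the genome build, the annotation release and the read filters are not given in the sources used here. The authors deposited estimated counts per gene (expected counts, unscaled, with 2 decimals), and 3053 of the 35134 genes held a fractional count in at least 1 library (more than 1e-09 from a whole number), which arises when a read is divided among genes or copies. The authors also deposited the same genes and libraries as TPM, which is relative to transcript length and to the library total. Both tables name their columns by sample title, and all 12 columns were used. Poly(A) selection and a fixed total mean that values are relative within a library, so that a few abundant transcripts lower all others.

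Identifiers are printed as in the files without their leading "gene:". None of them (0) matched the reference table of gene names, so the 30 gene lists fixed before the data were examined could not be matched, no set test was run, and names, functions and coordinates are not reported. In the grapevine naming scheme the digits after "Vitvi" give the chromosome, with 00 for sequence not placed on one; no coordinates were used. With no names, the rule fixed before the data were examined allows at most 2 identifiers that rose and 2 that fell. They were taken as the largest log2 changes among genes with adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the groups. Other genes are described by their rank in abundance, which was chosen after the values were seen, as were the abundance classes. Ranks and classes use the mean CPM of the 6 libraries unless 1 treatment is named.

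Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr by treatment (minimum count 10, minimum total 15), which kept 16030 genes holding 99.85 to 99.92% of the counts of each library. Libraries were scaled by TMM, whose factors were 1.05 to 1.06 for urea and 0.932 to 0.969 for GDPH. The test was edgeR's quasi-likelihood F test with the robust option, GDPH against urea, with Benjamini-Hochberg adjustment and a threshold of 0.05; a 2-fold threshold (absolute log2 fold change of at least 1) was set beside it. The standard error of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 0.217. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6 were used.

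Depth ran from 15092687 to 18763377 counts per library, so that 3 counts, the limit that a count of 0 allows, correspond to between 0.160 and 0.199 CPM; this covers counting error only. No 2 libraries of a treatment agreed within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts was at least 14.5, so no library is a repeat deposit of another. That they are separate samples rests on the labels. The same fit was tested on simulated counts for this comparison over 16030 genes, with the measured means, library sizes and dispersions and 200 changed genes. It recovered 58 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, with 12 false calls. The simulated libraries were independent, and far fewer genes changed than were called in the data. These rates therefore do not give the sensitivity of the real comparison.

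Urea and GDPH libraries share replicate numbers. After centring each treatment, libraries of the same number deviated together, with correlations across genes of 0.337, 0.426 and 0.193 for replicates 1, 2 and 3 against -0.320 to 0.008 for other pairs. Centring makes the 3 deviations of a treatment sum to 0, which pushes the other pairs towards negative values. Few matchings of 3 with 3 libraries are possible, so the check is weak. The numbers were treated as a possible pairing, fitted as a block beside the main fit. Any pairing rests on this check of the data. The labels describe a block layout and do not say that the number is the block. The fit without the block was fixed as the main one before the data were examined.

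Alternatives listed before the data were examined were RLE factors, library totals alone, DESeq2, limma-voom, no filter, a filter of 5 CPM in 3 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate block, edgeR without the robust option and each library left out. Alternatives chosen after seeing the data used limma-trend on log2(CPM + 1) with TMM, left out genes with fractional counts or the 10 most abundant genes, or removed from each library, by lowess with a span of 0.3, a trend with relative transcript length or with mean abundance, with and without the block. Relative length was the ratio of count to TPM at 0.5 TPM or more, available for 99.6% of tested genes. Shares of counts were compared by a two-sided exact permutation test. Consecutively numbered identifiers were compared with shuffles of the calls within 10 strata of abundance, 10000 for the counts given and 1000 for each alternative. That procedure was tested with 999 shuffles on shuffled calls, where it gave a permutation p of 0.257, and on 150 planted pairs, where it gave a permutation p of 0.001, both over 16030 genes.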

Results

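The transcriptome of deseeded table grape berries was measured by RNA-seq in 6 libraries of the early black-skinned cultivar Black Magic (Vitis vinifera). Vines received a corn gluten-derived protein hydrolysate (GDPH), a mixture of peptides and amino acids used as a biostimulant, or urea as the control, both supplied to the soil with the irrigation water at veraison, the onset of ripening, and both carrying 1.25 kg of nitrogen per hectare. Each library came from 1 plot of 7 vines, and 3 of the 4 plots per treatment were sequenced 14 days after application. The replicates were therefore separate plots of one vineyard. No library came from untreated vines, so rises and falls below are relative to urea. Which of the treatments moved a gene cannot be told. The 3 urea libraries held 15631539, 15092687 and 16390121 estimated counts, and the 3 GDPH libraries held 15959768, 18763377 and 18350350. Of 35134 annotated genes, 22619 had a count in at least 1 library and 16030 were abundant enough to be tested. The genes are given as annotation identifiers without names, so gene families and pathways were not analysed here.

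The libraries separated by treatment. The first principal component of log2 CPM, the counts scaled to the library, carried 52.4% of the variance and placed the 3 GDPH libraries on one side, at 26.4 to 67.1, and the 3 urea libraries on the other, at -52.1 to -21.9. The second component carried 19.7% and set urea replicate 1 apart, at 53.7 against -25.8 to 9.99 in the other libraries. Pearson correlations of log2 CPM across genes ran from 0.954 to 0.982 within treatments and from 0.918 to 0.961 between them.

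**Figure D1:**
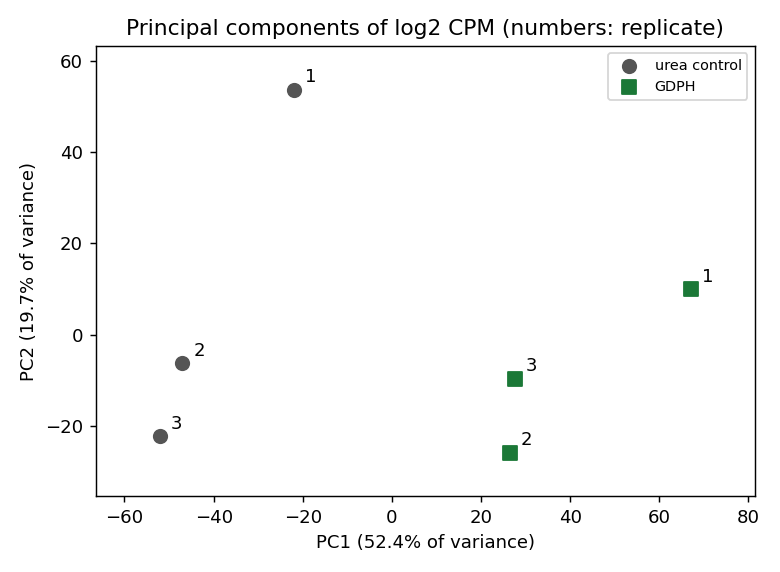
Principal components of log2 CPM over 16030 genes, with PC1 and PC2 in arbitrary units on the axes; each point is 1 library, circles are urea control, squares are GDPH, and numbers are replicates. The GDPH libraries lie at 26.4 to 67.1 on PC1 and the urea libraries at -52.1 to -21.9.

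The first comparison asked which berry transcripts differed between vines given the hydrolysate and vines given the same dose of nitrogen as urea. In GDPH berries 1034 genes were higher and 1319 were lower than in urea berries, together 2353 genes or 14.7% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 against 3). With TMM scaling and all abundances together, the called rises were smaller than the called falls. The median log2 fold change was 0.61 among higher genes and -0.995 among lower genes. Averaged over the 6 libraries, genes that rose had a median of 58.7 CPM, genes that fell 17.5 CPM and all tested genes 17.7 CPM. In the urea libraries alone the medians were 46.4, 23.2 and 17.97 CPM. At a change of at least 2-fold, 250 genes were higher and 655 were lower, the latter 72.4% of these 905 genes. With 1 library left out these counts were 138 higher and 219 lower without urea replicate 2 (61.3% lower), 171 and 266 without GDPH replicate 2 (60.9%), 181 and 389 without GDPH replicate 1 (68.2%), 210 and 418 without urea replicate 3 (66.6%), 226 and 493 without urea replicate 1 (68.6%), and 206 and 551 without GDPH replicate 3 (72.8%). Changes of at least 8-fold were seen in 26 higher and 50 lower genes. The difference in size between rises and falls depended on the scaling. With TMM 250 of 1034 higher and 655 of 1319 lower genes reached 2-fold. With library totals alone 189 of 534 and 922 of 2289 did, and on log2(TPM + 1) 145 of 395 and 954 of 3856. The difference also depended on abundance. With TMM 91 of 115 higher and 348 of 430 lower genes between 1 and 10 CPM reached 2-fold. Between 10 and 100 CPM 94 of 546 and 212 of 651 did, and between 100 and 1000 CPM 37 of 323 and 41 of 179. From 1000 CPM 12 of 34 and 2 of 7 did. In simulated counts 3 of 30 2-fold changes were called under 10 CPM and 55 of 70 from 10 CPM.

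All 2353 called genes had their 3 GDPH values entirely above or entirely below their 3 urea values. With 3 against 3 libraries a gene with overlapping groups is rarely called, so this adds no separate support. Among all tested genes this held for 38.3%, where chance gives 10%. Genes are not independent, so the difference between these shares was not tested. With the replicate number as a block the count was 3534 genes, 1573 higher and 1961 lower, and 2293 of the 2353 genes were called again, all in the same direction. The balance of higher and lower genes depended on the scaling. Scaling to library totals alone moved the median log2 fold change by -0.16 and gave 534 higher and 2289 lower genes, and the deposited TPM values, tested with limma at a pseudocount of 1, moved it by -0.27 and gave 395 higher and 3856 lower. Leaving out 1 library in turn gave between 555 genes (without urea replicate 2) and 1443 genes (without GDPH replicate 3), against 709 without GDPH replicate 2, 1393 without GDPH replicate 1, 1403 without urea replicate 3 and 1428 without urea replicate 1.

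**Figure D2:**
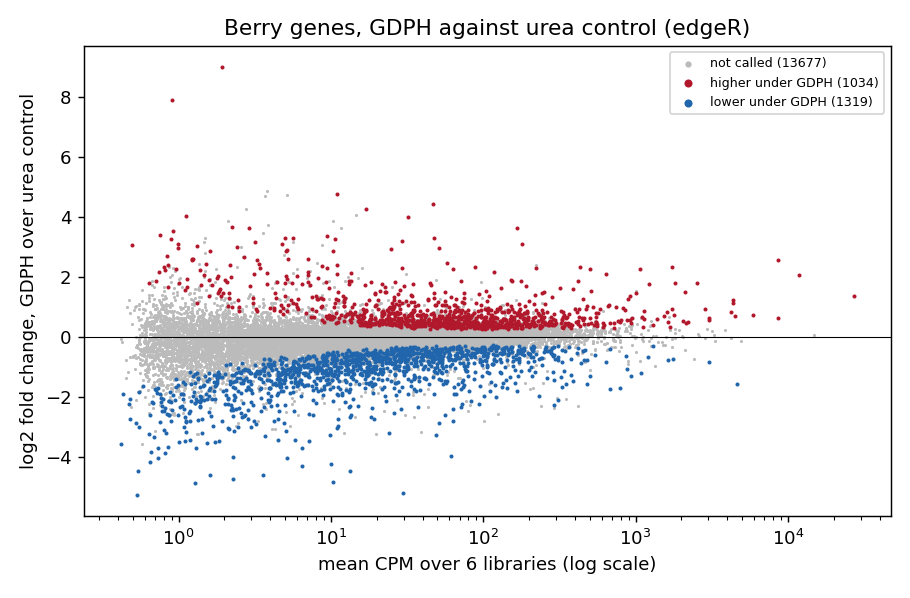
Log2 fold change of GDPH over urea control (vertical axis) against mean CPM over the 6 libraries (horizontal log axis) for 16030 genes; each point is 1 gene, red is higher (1034 genes), blue is lower (1319 genes) and grey is not called by edgeR. Red points extend to the most abundant genes, and the blue points are the more numerous among falls and rises of at least 2-fold (655 against 250).

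Among called genes averaging at least 2 CPM and without overlap between the groups, 2 had the largest rises. Vitvi14g01489, on chromosome 14 by its identifier, had 0.770 ± 0.569 CPM under urea and 21.3 ± 18.8 CPM under GDPH (SD, n = 3), a log2 fold change of 4.78 (SE 0.86, edgeR adjusted p = 0.019). Its GDPH values were uneven, at 43.0, 11.8 and 9.12 CPM. Vitvi08g01547, on chromosome 8, rose from 4.13 ± 1.39 to 89.0 ± 3.21 CPM (SD, n = 3), which is 21.5-fold higher (log2 fold change 4.43, SE 0.22, edgeR adjusted p = 0.0014). Its GDPH values of 92.7, 86.8 and 87.5 CPM agreed closely.

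Vitvi04g00501, on chromosome 4, fell from 58.0 ± 6.04 CPM under urea to 1.55 ± 1.20 CPM under GDPH (SD, n = 3). This gene was 36.7-fold lower (log2 fold change -5.20, SE 0.44, edgeR adjusted p = 0.0040) and was read 871 to 1126 times in the urea libraries and 11 to 52 times in the GDPH libraries. Vitvi18g00792, on chromosome 18, fell from 19.9 ± 14.1 to 0.668 ± 0.481 CPM (SD, n = 3), with a log2 fold change of -4.85 (SE 0.76, edgeR adjusted p = 0.014). Its urea values were spread from 9.06 to 35.8 CPM, and between 2 and 19 reads were counted in the GDPH libraries. None of these 4 genes held a fractional count, the mark of reads divided among genes. Vitvi08g01547 and Vitvi04g00501 passed the test in each of 23 alternative settings, with log2 fold changes of 3.96 to 4.72 and -6.06 to -4.63. The lowest of the latter, 66.9-fold, was without GDPH replicate 3. Over the same settings the log2 fold change ran from 3.38 to 5.53 for Vitvi14g01489, with 3.76 (13.6-fold) without GDPH replicate 1 and 5.53 without urea replicate 1, and from -5.35 to -3.19 for Vitvi18g00792, with -4.11 (17.3-fold) without urea replicate 1. Vitvi14g01489 missed the test with limma-voom (adjusted p = 0.082), without urea replicate 2 (edgeR adjusted p = 0.076) and without urea replicate 3 (edgeR adjusted p = 0.056), and Vitvi18g00792 missed it with limma-voom (adjusted p = 0.060) and without GDPH replicate 2 (edgeR adjusted p = 0.054).

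**Figure D3:**
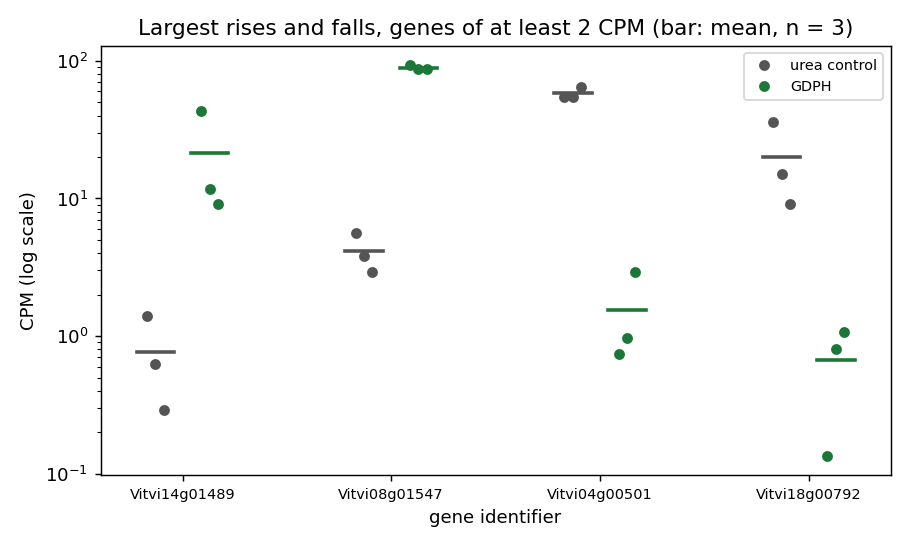
CPM on a log axis of the 2 genes with the largest rise and the 2 with the largest fall among called genes averaging at least 2 CPM; each point is 1 library, grey is urea control, green is GDPH, and the horizontal bar is the mean of 3. Absence of overlap between the groups was a condition for choosing the 4 genes. The GDPH points of Vitvi08g01547 lie between 86.8 and 92.7 CPM.

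Called genes with a change of any size were classed by the mean CPM of all 6 libraries, with TMM scaling. Rises then outnumbered falls among abundant genes, and falls outnumbered rises among weakly expressed ones. Of 89 genes averaging 1000 CPM or more, 34 rose and 7 fell, so that 82.9% of the called genes were higher (exact 95% binomial interval 67.9 to 92.8%). Between 100 and 1000 CPM 323 genes rose and 179 fell (64.3% higher, interval 59.98 to 68.5%), and between 10 and 100 CPM 546 rose and 651 fell (45.6% higher, interval 42.8 to 48.5%). Of 5088 genes between 1 and 10 CPM, 115 rose and 430 fell (21.1% higher, interval 17.7 to 24.8%), and of 896 genes under 1 CPM, 16 rose and 52 fell. The intervals treat genes as independent, which they are not. At a change of at least 2-fold the excess of rises between 100 and 1000 CPM was absent, with 37 higher and 41 lower. From 1000 CPM 12 were higher and 2 lower at that threshold. Between 10 and 100 CPM 94 were higher and 212 lower, and between 1 and 10 CPM 91 were higher and 348 lower. The median log2 fold change of all genes of a class ran from -0.23 under 1 CPM and -0.15 between 1 and 10 CPM to 0.12 between 100 and 1000 CPM and 0.24 from 1000 CPM. With library totals alone it was -0.31 between 1 and 10 CPM, -0.04 between 100 and 1000 CPM and 0.08 from 1000 CPM. With classes by the urea libraries alone it was 0.26 under 1 CPM and -0.15 between 1 and 10 CPM. It was then 0.08 between 100 and 1000 CPM and 0.05 from 1000 CPM. A change in the GDPH libraries moves the mean by which a gene is classed, so the classes were also formed from the urea libraries alone. From 1000 CPM 25 genes then rose and 12 fell, between 100 and 1000 CPM 252 rose and 224 fell, between 10 and 100 CPM 577 rose and 688 fell, and between 1 and 10 CPM 127 rose and 386 fell. Under 1 CPM the balance turned over, with 53 higher and 9 lower. A gene this weak under urea could pass the filter through its GDPH counts, so this class favours rises by construction. Classes from the GDPH libraries alone lean the other way under 1 CPM, with 2 higher and 171 lower. From 1000 CPM they held 43 higher and 5 lower. Classing by 1 treatment is therefore not free of bias either. The excess of rises between 100 and 1000 CPM depended on the scaling as well. In that class 153 genes rose and 303 fell with library totals alone, 98 rose and 501 fell on log2(TPM + 1), and 177 rose and 231 fell once a trend with mean abundance had been removed from each library. From 1000 CPM the same 3 settings gave 27 higher and 14 lower, 22 higher and 20 lower, and 23 higher and 14 lower. Between 1 and 10 CPM falls prevailed in all 3, with 81 higher and 624 lower, 89 higher and 1102 lower, and 163 higher and 293 lower. Leaving out 1 library reduced the counts. Between 100 and 1000 CPM 61 genes rose and 57 fell without urea replicate 2, 86 rose and 66 fell without GDPH replicate 2, and 166 rose and 133 fell without urea replicate 1. The other 3 omissions left 195 to 232 higher and 122 to 126 lower in that class. From 1000 CPM 17 rose and 2 fell without urea replicate 2, and 19 rose and 3 fell without GDPH replicate 2. Between 1 and 10 CPM the 6 omissions left 34 to 74 higher and 79 to 266 lower.

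**Figure D4:**
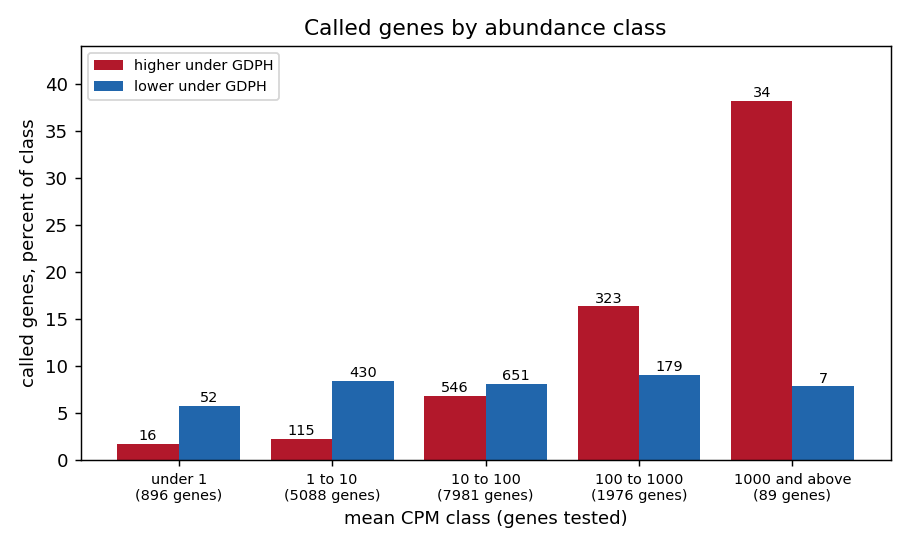
Genes called higher (red) or lower (blue) under GDPH as a percent of the genes tested in each class of mean CPM over the 6 libraries; numbers above the bars are genes. Lower genes outnumber higher ones 430 to 115 between 1 and 10 CPM, and higher genes outnumber lower ones 34 to 7 from 1000 CPM.

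The most abundant transcripts of the berry accounted for a larger part of the GDPH libraries. Of the 20 most abundant genes by the mean of all 6 libraries, 11 rose, 2 fell and 7 did not pass the test. Ranked by the urea libraries alone, 8 of the top 20 rose, 2 fell and 10 did not pass, and ranked by the GDPH libraries alone 13 rose, 0 fell and 7 did not pass. The ranks that follow are by the mean of all 6. The most abundant of all, on chromosome 5, rose from 15217 ± 948 to 39023 ± 1295 CPM (SD, n = 3), which is 2.56-fold (edgeR adjusted p = 0.0014). The gene of rank 3, on chromosome 19, rose 4.25-fold from 4485 ± 471 to 19041 ± 2524 CPM, and the gene of rank 4, on chromosome 5 and of rank 22 in the urea libraries, rose 6.02-fold from 2458 ± 288 to 14801 ± 3726 CPM (SD, n = 3; edgeR adjusted p = 0.0014 and 0.0028). The gene of rank 4 held whole counts in every library, whereas the 3 genes with adjoining identifier numbers that also rose held fractional ones. The gene of rank 8, on chromosome 19, fell from 6984 ± 1531 to 2353 ± 558 CPM (SD, n = 3), with a log2 fold change of -1.57 (edgeR adjusted p = 0.0091). The gene of rank 2, on chromosome 18, was at 14451 ± 229 CPM under urea and 15089 ± 1593 CPM under GDPH (SD, n = 3), and its log2 fold change of 0.06 did not pass the test (SE 0.10, edgeR adjusted p = 0.73). Without urea replicate 2 or without GDPH replicate 2, 7 of the 20 genes passed as higher and 1 as lower, and without GDPH replicate 1 10 passed as higher and 1 as lower. On the TPM scale 8 passed as higher and 4 as lower.

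In each library the 10 most abundant genes together took 7.34% ± 0.216 of the counts under urea and 12.2% ± 0.484 under GDPH (SD, n = 3), a difference of 4.84 percentage points. The single most abundant gene took 1.61% ± 0.0920 under urea and 3.68% ± 0.0788 under GDPH, and the 100 most abundant took 22.5% ± 0.537 and 28.2% ± 0.782 (SD, n = 3). Each of the 3 shares was higher in all 3 GDPH libraries than in all 3 urea libraries, and the two-sided exact permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow. Expressed as TPM, which divides by transcript length, the share of the 10 most abundant genes was 13.9% ± 0.386 under urea and 24.3% ± 0.858 under GDPH (SD, n = 3).

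**Figure D5:**
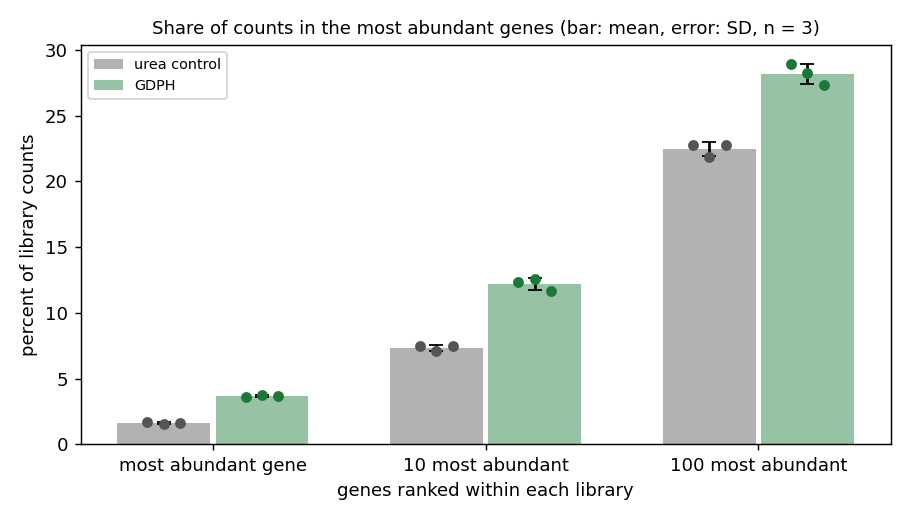
Percent of the library's counts (vertical axis, from 0) taken by the most abundant gene, the 10 most abundant and the 100 most abundant, ranked within each library; bars are means, error bars are SD, points are the 3 libraries, grey is urea control and green is GDPH. The 10 most abundant genes take 7.34% under urea and 12.2% under GDPH.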

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

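Of the 6 counts of changed genes (all, higher and lower, with and without the 2-fold threshold) under 23 alternatives each, 97 values lay within 1.5 times the value reported and 41 did not. Library totals alone gave 534 higher and 2289 lower genes. The limma test on log2(TPM + 1) gave 4251 changed genes, 395 higher and 3856 lower, and 145 higher at least 2-fold. On log2(TPM + 0.1) it gave 4168, 379 higher and 3789 lower, and 1457 at least 2-fold with 1288 lower. The median log2 fold change moved by -0.16, -0.27 and -0.28, and 1852, 1691 and 1686 of the 2353 genes were called again, all in the same direction. With totals this shift towards lower follows by construction. The TPM settings changed both the scale and the test; limma-trend on log2(CPM + 1) with TMM, which changed the test and kept the scaling, gave 2495 genes, 1092 higher and 1403 lower. The replicate block gave 3534 genes with 1573 higher, and with the length trend removed as well 3644 with 1753 higher; the block changed no call of the 4 named genes. Leaving out 1 library gave 555 to 1443 changed genes, 236 to 641 higher and 319 to 869 lower, and at least 2-fold 357 to 757, 138 to 226 higher and 219 to 551 lower. The lowest count was without urea replicate 2, where 546 of the 2353 genes were called again, and the next without GDPH replicate 2; fewer samples lower the power, and why these 2 libraries cost more than the others was not tested. Among 444 further values, 300 stayed and 139 moved, counts by the same factor, the share of the 10 most abundant genes by 1 SD and the 4 named genes by their call, which was missed 5 times without a change of sign. The counts were of abundance classes, the 20 most abundant genes, consecutive identifiers and uneven chromosomes. The majority of calls in an abundance class reversed in 5 of 23 alternatives between 100 and 1000 CPM, which were library totals, both TPM settings and the abundance trend removed with and without the block, and in 2 between 10 and 100 CPM, which were the length trend removed without the block (636 higher, 620 lower) and with it (1023 higher, 992 lower). DESeq2 called 3209 genes, 2339 of them among the 2353. The gene list tests and their alternatives were not run, since no identifier matched a name. The limma-trend setting on CPM and those without fractional counts, without the 10 most abundant genes or with a trend removed were chosen after seeing the data. Of simulated 2-fold changes, 3 of 30 were called under 10 CPM and 55 of 70 from 10 CPM, with far fewer changed genes than in the data.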

Other observations

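The tests of consecutive identifiers, shared reads, abundance and length trends, scaling shift, replicate 1, other splits, chromosomes and effective length were chosen after the main results were seen. Genes with neighbouring identifier numbers changed together more often than shuffled calls. Of 7706 pairs of consecutively numbered genes, 120 pairs had both members called in the same direction, against 89.1 expected and a permutation p of 0.001. Pairs called in opposite directions were not in excess, at 80 against 86.5 expected (permutation p = 0.786). There were 6 runs of at least 3 consecutive genes that all rose and 3 runs that all fell. The longest runs held 4 genes, and both rose. In the run on chromosome 5, log2 fold changes were 2.59 to 4.003 over mean levels of 7.12 to 8629 CPM, and it includes the gene of rank 4 in mean abundance over the 6 libraries, which is of rank 22 under urea. In the run on chromosome 7, log2 fold changes were 0.41 to 1.08.

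Reads divided between near-identical neighbours could make such pairs move together, and 3 of the 4 genes in the chromosome 5 run held fractional counts. Among the 14077 genes with whole counts in every library the excess was still there, at 113 pairs against 85.1 expected (permutation p = 0.0015), which argues against shared reads as the whole cause, while the chromosome 5 run itself stays open. For chance placement of the calls the only test is the permutation p of 0.001 that defined the pattern, so it is no second test. The ratio of observed to expected pairs stayed between 1.14 and 2.38 in 23 alternatives, each with a permutation p under 0.05. These alternatives reuse the same 6 libraries and count a gene that a setting left out as not called, so they are not independent. The number of pairs itself fell to 12 without urea replicate 2 (5.04 expected), 18 without GDPH replicate 2 (8.29 expected) and 47 to 52 with another library left out. What else would join neighbouring genes was not tested, since the identifiers carry no gene family.

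The excess of falls among genes changed at least 2-fold, 655 against 250, is a second pattern. Leaving out the 10 most abundant genes gave 650 lower and 246 higher (72.5% lower), but that setting hardly moved other genes, so it does not test whether a few abundant genes distort the scaling, which stays open. A trend of fold change with abundance, removed per library, left 64.9% lower (exact 95% binomial interval 61.5 to 68.1%). Such a trend may account for a part of the excess, and as fitted here it did not account for all of it. The interval treats genes as independent, which they are not. The mean abundance used for the trend also includes the GDPH libraries, so how much a trend accounts for stays open. A common scaling error would need to shift every log2 fold change by 0.309 upwards to balance the calls, taken without refitting. The count scalings tried differed from TMM by at most 0.164, and that one downwards. Their spread does not bound the true error, so a scaling error of the size needed is not excluded. The treatment itself stays open as an explanation, and no biological explanation was tested.

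Replicate 1 of both treatments lay towards the GDPH side of its group. The difference between replicate 1 and each other replicate of its treatment was regressed across genes on a treatment effect computed from the remaining library of that treatment and the libraries of the other treatment. The 4 slopes were 0.164 and 0.199 for urea replicate 1 and 0.193 and 0.236 for GDPH replicate 1, with r across genes of 0.171 to 0.266, and genes are not independent replicates. Between replicates 2 and 3 the slopes were -0.069 for urea and -0.012 for GDPH. With the length trend removed the smallest of the 4 slopes was 0.167, which argues against a length trend such as RNA breakage gives. A difference shared by both plots numbered 1 remains open and was not tested, because the labels give no plot positions.

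Other splits of the 6 libraries into 3 and 3 were also tested. Of the 10 splits, 1 gave as many changed genes as the real one, which was the real split itself, with 2353 genes, and the highest of the others gave 0; at least 2-fold the real split gave 905, again 1 split of 10, and the highest other 0. The 3 other splits that part every same-numbered pair gave 0 as well. Apart from the real split, every split puts libraries of both treatments in each group. The treatment difference then adds to the spread within groups, which can by itself remove the calls. The counts of 0 therefore do not show how many calls chance would give. With 10 splits no share under 0.05 is possible.

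The share of tested genes that changed ran from 12.3% to 17.8% over the 19 chromosomes. Chromosome 8 had the highest share, 187 of 1050 genes (Fisher's exact test against all other genes, adjusted p = 0.0385 over 20 groups of identifiers), but it passed in only 8 of 23 alternatives, with adjusted p from 0.00993 to 0.673. Identifiers not placed on a chromosome had 13 called of 181 (adjusted p = 0.0385) and passed in 10 of 23 alternatives, with adjusted p from 4.6e-08 to 0.673. In both tallies a gene that a setting left out was counted as tested and not called. The Fisher adjusted p of 4.6e-08 came from the setting without genes holding fractional counts, so it partly reflects this counting. With the replicate block neither group passed (Fisher adjusted p = 0.0661 for each). Fisher's test treats genes as independent, although neighbouring genes were called together more often than in shuffled calls. It also takes no account of abundance, while the share of genes called ran from 7.59% under 1 CPM to 46.1% from 1000 CPM. The ratio of count to TPM follows the effective length of a gene's transcripts, which depends on a library's fragment lengths as well as on isoforms. It differed between the groups without overlap in 33.5% of 10700 genes with at least 5 TPM in every library, where chance gives 10%. Genes are not independent, and the ratio cannot separate isoforms from fragment lengths, so no change of transcript length is concluded. These shifts were small: 14 genes had non-overlapping groups and a shift of the ratio over 0.1 on the log2 scale, and the largest such shift was 0.195.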
